A study of Homo sapiens with 12 samples.

How the data were processed

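RNA from Huh7 and PLC/PRF/5 cells with lenvatinib or DMSO was measured in 12 libraries, 3 per group, assigned to the 4 groups from the sample titles. Per the labels, RNA was taken with an RNeasy kit, the mRNA was purified and fragmented, cDNA was primed with random hexamers, and DNA nanoballs were read on a BGIseq500 as single ends of 50 bases. The submitters' processing notes name HISAT2 and hg19, while the HISAT2 version, the counting program, the annotation and the strand setting are not given in the sources used here. The series table holds, per the file headers, a count column and an FPKM column for each library; both were made by the authors. It has 40825 lines with a symbol and no gene identifier, 35612 distinct symbols, 2803 symbols on several lines, and 2016 lines at 0 in all 12 libraries. A further 12 columns, of 6 libraries of another cell line, were not used here.

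The test planned before the data were examined was limma on log2(FPKM + 1), since only FPKM were thought to be in the table. As the table also holds counts, the deposited counts were tested in its place with edgeR's quasi-likelihood F test (robust), TMM factors and 1 coefficient per group, and the planned limma fit became an alternative. The result for STX6 depends on this switch: the planned test calls it in both lines and the count test does not. The 15587 genes with a mean FPKM of at least 0.5 were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lines that share a symbol were kept apart. The common biological coefficient of variation was 0.234. Standard errors are the log2 fold change over the square root of F. The comparisons were lenvatinib against DMSO in each line, the difference of these changes (PLC/PRF/5 minus Huh7), and PLC/PRF/5 against Huh7 under DMSO. Sets were 33 lists fixed before the data were examined, tested with camera (preset correlation 0.01) where at least 5 members were measured, and again with an estimated correlation. Unless stated otherwise, the adjusted p of a list is that with the preset correlation. With an estimated correlation it was larger for every list called. Named genes are STX6, up to 10 of the largest changes each way (8 for the difference) with no replicate overlap and a mean FPKM of at least 5, up to 4 members of smallest adjusted p per list with a mean FPKM of at least 1, and the measured lenvatinib receptors; the text describes part of them. STX6 alone was also compared by exact permutation. Gene positions and exon overlaps are from GENCODE 29 on GRCh38, another build than the submitters'.

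Total counts ran from 70236175 to 75820318 per library. A gene with 100 counts carries a counting error of 10.0%, and the floors cover counting error only. Replicate numbers did not pair the samples: residual correlations of libraries with the same number ran from 0.00363 to 0.0260 in Huh7, -0.0183 to -0.00853 in PLC/PRF/5 and -0.00357 to 0.0494 across the lines. On simulated data, 100 genes were changed 1.5-fold and another 100 were changed 2-fold in each run. The test found 33 and 64 of them in Huh7, 28 and 59 in PLC/PRF/5, 4 and 37 for the difference and 14 and 64 under DMSO. False calls were 6 of 103, 4 of 91, 2 of 43 and 1 of 79 calls. Each comparison was run under 30 other settings, and the difference under 29, as a fit of only the groups compared gives none; 6 of them were added after the data were seen. The comparison of FPKM with counts (tested on simulated data: 20 of 20 altered values found, 0 false), the whole-number test and the definition of single-library gaps were chosen after the data were seen. The splits for the difference were redrawn in another way after a first run, and the decision rules of the depth and slope tests were tightened after their values were seen. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.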

Results

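RNA was sequenced from Huh7 and PLC/PRF/5, established human hepatocellular carcinoma lines, grown with lenvatinib or with its solvent DMSO. Lenvatinib is an oral inhibitor of receptor tyrosine kinases that blocks the VEGF and FGF receptors, PDGFRA, KIT and RET. The 12 libraries formed 4 groups of 3 replicates, and the dose and the length of the exposure are not given in the sources used here. Total counts per library ran from 70236175 to 75820318. Transcripts of the mitochondrial genome took 5.64 ± 0.0600% of the counts in Huh7 with DMSO and 6.58 ± 0.281% with lenvatinib (SD, n = 3), and 10.5 ± 0.181% and 11.1 ± 0.145% in PLC/PRF/5. The first principal component held 82.0% of the variance and separated the lines, and the second held 3.99% and separated lenvatinib from DMSO in both. The replicates are not said to come from separate cultures, so the p-values measure the spread between these samples, which may be technical. Changes below are log2 fold changes with their standard errors, from edgeR fits to 3 libraries per group.

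Syntaxin 6 (STX6), a SNARE protein of the trans-Golgi network and endosomes, is the gene that the study links to autophagy and to resistance against lenvatinib. It lies on chromosome 1 from 180972712 to 181023121 on the minus strand of GRCh38, where its exons overlap AL162431.2. In the counts, STX6 stood at 50.5 ± 3.78 CPM (TMM-scaled) in Huh7 with DMSO and 49.5 ± 4.55 with lenvatinib (SD, n = 3), a log2 fold change of -0.03 ± 0.50 with adjusted p = 0.985. In PLC/PRF/5 it stood at 57.5 ± 34.2 CPM with DMSO and 65.2 ± 31.5 with lenvatinib, a log2 fold change of 0.18 ± 0.50 with adjusted p = 0.852. Replicate 2 with DMSO and replicate 3 with lenvatinib held 1229 and 2105 STX6 counts, against 5470 to 6515 in the other PLC/PRF/5 libraries. The FPKM values of the same libraries gave another picture. In Huh7 they were 6.50 ± 0.507 under DMSO and 36.5 ± 0.520 under lenvatinib (5.61-fold). In PLC/PRF/5 they were 9.41 ± 0.959 and 42.2 ± 1.49 (4.49-fold). With lenvatinib the counts imply only 5.87 to 6.85 FPKM in Huh7 and 3.94 to 11.5 in PLC/PRF/5. Every lenvatinib value, and that of PLC/PRF/5 replicate 2 with DMSO, lay above the implied one by a near whole number. The FPKM tests that follow include these offsets, so they cannot show a change of the transcript apart from them. On the FPKM, limma on log2(FPKM + 1), the test first planned, called STX6 higher with lenvatinib in Huh7 (2.32, adjusted p = 1.58e-08) and in PLC/PRF/5 (2.06, adjusted p = 5.00e-07). The same test called it higher in PLC/PRF/5 than in Huh7 under DMSO (0.47, adjusted p = 1.36e-04) and did not call the difference between the lines (-0.27, adjusted p = 0.101). An exact permutation test of the FPKM gave p = 0.1 in each line, the smallest value that 3 against 3 libraries allow. A fit of the Huh7 libraries alone put the count log2 fold change between -0.25 and 0.20 (95% interval), while that for PLC/PRF/5 ran from -1.65 to 2.05. Neither the difference between the lines (0.21 ± 0.70, adjusted p = 0.901) nor the level under DMSO in PLC/PRF/5 against Huh7 (0.19 ± 0.50, adjusted p = 0.759) passed the test on counts. With single libraries left out, STX6 was not called in the counts, but its values moved. In PLC/PRF/5 the change was -0.24 without replicate 2 with DMSO, 0.44 and 0.47 without replicates 1 and 3, and -0.016, -0.054 and 0.54 without replicates 1, 2 and 3 with lenvatinib. The difference was 0.46, -0.21, 0.50, 0.013, -0.025 and 0.57 without these libraries in the order of DMSO and then lenvatinib replicates 1 to 3. The level under DMSO was -0.075, 0.60 and -0.11 without PLC/PRF/5 replicates 1, 2 and 3, and 0.12 without Huh7 replicate 2. In Huh7 the change stayed between -0.081 and 0.044 with any library left out. Of 16 STX6-related SNARE genes, 2 rose and 2 fell in Huh7 (2 and 2 adjusted over the list alone). STX7 was at 0.31 ± 0.05 and VAMP8 at -0.37 ± 0.07. Of the same genes, 3 rose and 5 fell in PLC/PRF/5 (4 and 6 adjusted over the list alone), where VAMP4 was at 0.84 ± 0.15 and VAMP8 at -0.48 ± 0.07. As a set they were not called in Huh7 (adjusted p = 0.939) or in PLC/PRF/5 (adjusted p = 0.849).

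**Figure D1:**
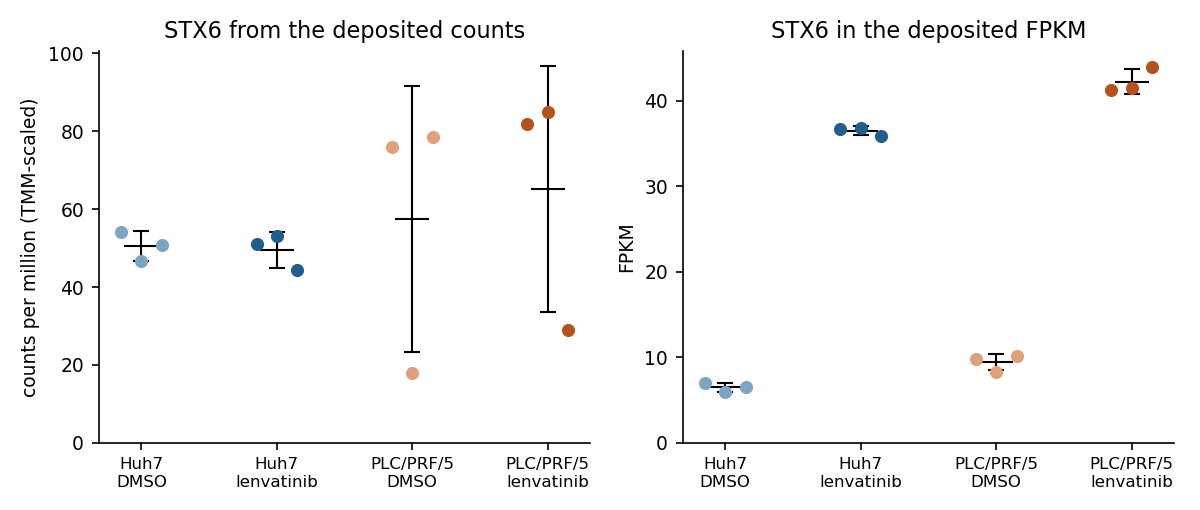
STX6 in each of the 12 libraries, from the counts (left panel, TMM-scaled CPM) and from the FPKM (right panel), by line and treatment, where points are libraries, black lines the mean and bars the SD (n = 3). The count means are 50.5 and 49.5 in Huh7 and 57.5 and 65.2 in PLC/PRF/5. The FPKM means are 6.50 and 36.5, and 9.41 and 42.2. Every lenvatinib FPKM, and that of PLC/PRF/5 replicate 2 with DMSO, lies above the FPKM implied by its count by a near whole number.

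The comparison of lenvatinib with DMSO in Huh7 asks which transcripts change in this line under the drug (n = 3 per group). The largest falls, in order, were those of SPRY4, DUSP6, CCN2, ETV5, ETV1, TCIM and ETV4, of which SPRY4, DUSP6, ETV5 and ETV4 are on the ERK pathway output list. SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, went from 66.1 ± 7.95 to 1.64 ± 0.502 CPM (SD), a log2 fold change of -5.34 ± 0.22, and the ERK phosphatase DUSP6 fell by 4.98 ± 0.20. The ETS transcription factors ETV5, ETV1 and ETV4 changed by -4.85 ± 0.14, -4.25 ± 0.19 and -4.02 ± 0.23, and the ephrin receptor EPHA2 by -3.50 ± 0.15. Among the largest rises were IL6R, the receptor for interleukin 6 (5.29 ± 0.42), the interferon-induced IFIT2 (3.15 ± 0.27), the xenobiotic-metabolising CYP1A1 (2.91 ± 0.24) and the stress-induced chromatin protein NUPR1 (2.85 ± 0.17).

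Of 18 measured genes of ERK output, 2 rose, 13 fell and 3 were not called (2 and 14 adjusted over the list alone; median -2.37, adjusted p = 2.87e-50). CCND1, the G1 cyclin D, changed by -2.004 ± 0.06, while the transcription factor MYC was among the 2 rises. Cell cycle genes fell almost throughout: 28 of 30 fell and none rose (30 fell adjusted over the list alone; median -0.79, adjusted p = 2.62e-29). They included the replication licensing factors MCM3 (-1.17 ± 0.07) and CDT1 (-1.35 ± 0.10) and the proliferation marker MKI67 (-0.82 ± 0.06). With an estimated correlation the ERK set had adjusted p = 0.00216 and the cell cycle set adjusted p = 0.00575. In the hypoxia and glycolysis list, 2 rose, 15 fell and 3 were not called (3 and 16 adjusted over the list alone; adjusted p = 4.13e-22). Examples are pyruvate dehydrogenase kinase PDK1 (-1.61 ± 0.08), the collagen hydroxylase P4HA1 (-1.26 ± 0.06) and the glycolytic enzyme PGK1 (-1.01 ± 0.05). Among YAP and TEAD targets, 2 rose, 9 fell and 6 were not called (2 and 9 adjusted over the list alone; adjusted p = 2.52e-17). Among them were the matrix protein CCN2 (-4.85 ± 0.11) and ANKRD1 (-3.29 ± 0.23). Chaperones of the endoplasmic reticulum also fell, 12 of 19 and none upward (14 fell adjusted over the list alone; adjusted p = 2.41e-08). They include the Hsp70 chaperone HSPA5 at -0.75 ± 0.03 and the disulfide isomerase PDIA4 at -0.70 ± 0.04. Mesenchymal and matrix genes had 2 rises and 5 falls (2 and 5 adjusted over the list alone). Members are thrombospondin THBS1 at -3.14 ± 0.20 and TGFB2 at -2.07 ± 0.14. The list was called downward (adjusted p = 0.00591) although its median was 0.08. Progenitor markers gave 1 rise and 5 falls (1 and 5 adjusted over the list alone; adjusted p = 0.00260). Examples are PROM1 (-2.24 ± 0.10) and the transcription factor SOX9 (-2.41 ± 0.14).

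In the opposite direction, 19 of 24 ATF4 and amino acid response genes rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 4.00e-14). Among them were asparagine synthetase ASNS (1.10 ± 0.09), ATF4 itself (0.57 ± 0.05) and mitochondrial PEP carboxykinase PCK2 (0.97 ± 0.12). NRF2 and ferroptosis genes rose in 16 of 22 cases with 1 fall (16 and 1 adjusted over the list alone; adjusted p = 3.38e-14). They include the aldo-keto reductase AKR1C2 (2.19 ± 0.12), heme oxygenase HMOX1 (1.37 ± 0.10) and ferritin heavy chain FTH1 (0.83 ± 0.05). Hepatocyte genes numbered 14 rises and 2 falls among 26 (17 and 3 adjusted over the list alone). Members are the fibrinogen chains FGG (1.93 ± 0.04), FGB (1.90 ± 0.07) and FGA (1.47 ± 0.06) ahead of APOE (0.78 ± 0.05). That list had adjusted p = 2.66e-12 with the preset correlation and adjusted p = 0.0603 with an estimated correlation. Drug and bile acid metabolism genes rose in 7 of 11 cases with 1 fall (7 and 1 adjusted over the list alone; adjusted p = 3.98e-05). Examples are the organic anion exporter ABCC2 (1.32 ± 0.06) and the sulfotransferase SULT2A1 (2.72 ± 0.43). Interferon response genes had 7 rises and 1 fall among 18 (8 and 2 adjusted over the list alone; adjusted p = 2.65e-05). Among them were the RNA sensor IFIH1 at 2.65 ± 0.17 and IFIT3 at 3.98 ± 0.42. Lysosomal genes rose in 15 of 30 cases and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 1.18e-04). They include the sialidase NEU1 (0.88 ± 0.05) and acid glucosidase GAA (0.82 ± 0.09). The 35 autophagy machinery genes were not called as a set (adjusted p = 0.322). Members are 6 rises and 2 falls (6 and 2 adjusted over the list alone) that included the cargo receptor SQSTM1 (1.39 ± 0.04). Cholesterol synthesis genes rose in 11 of 25 cases and fell in 2 (13 and 2 adjusted over the list alone), HMG-CoA synthase HMGCS1 by 0.63 ± 0.04. The set had adjusted p = 0.00205, and adjusted p = 0.184 with an estimated correlation. Heat shock genes rose in 8 of 14 cases with no fall (9 and 0 adjusted over the list alone), HSP90AA1 by 0.64 ± 0.08. As a set they had adjusted p = 0.00260, and adjusted p = 0.199 with an estimated correlation. Of the receptors that lenvatinib targets, FGFR4 (-0.36 ± 0.13), FGFR1 (-0.28 ± 0.15) and FGFR3 (0.17 ± 0.25) did not pass the test, and PDGFRA fell (-3.24 ± 0.96, adjusted p = 0.0319) from 27.0 ± 1.14 to 2.85 ± 0.723 CPM (0 and 2 adjusted over the list alone for these receptors). The PDGFRA call was lost with any of the 6 Huh7 libraries left out (adjusted p = 0.0703 to 0.0919). Its standard error rests on a spread shared with the PLC/PRF/5 libraries, some of which had no PDGFRA count. It is thus not the spread of the Huh7 replicates alone.

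In all, 3850 of 15587 genes were called in Huh7 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1773 higher and 2077 lower with lenvatinib, of which 702 changed at least 2-fold (310 higher, 392 lower). The share of higher genes, 46.1%, was 51.1% with library totals alone, 51.2% with limma on log2(FPKM + 1) and 52.4% with quality weights. Of the 29 lists tested, 19 were called, and 12 were with an estimated correlation. The groups did not overlap in 41.6% of genes, against 10% by chance for 3 against 3. Other genes among the largest changes were the calcium-binding S100A14 (2.83 ± 0.26), the plasmin inhibitor SERPINF2 (2.40 ± 0.26), the ubiquitin-like UBD (2.68 ± 0.34), the glucuronosyltransferase UGT2B15 (5.21 ± 0.67), TCIM (-4.14 ± 0.17), the long non-coding LINC02331 (-3.80 ± 0.16) and TACC1 (-3.30 ± 0.57), whose counts had a gap of over 2-fold in a single library. SNORD36A, a small nucleolar RNA at 1.02 ± 0.406 CPM with lenvatinib, had 1 count in each DMSO library, so no fold is given (adjusted p = 0.0415), and its call was lost with any Huh7 library left out (adjusted p = 0.0622 to 0.117). Exons of IFIT2, UBD, DUSP6, CCN2, CCND1, ASNS, PDK1, P4HA1, PGK1, THBS1, TGFB2, FTH1, APOE, SQSTM1, HMGCS1, FGFR1 and PDGFRA overlap another annotated gene and UGT2B15 and AKR1C2 have close paralogs, so their counts are uncertain as long as the strand and the handling of shared reads are not known. On the log2(FPKM + 1) scale, which compresses low levels, the changes were smaller (SPRY4 -2.96, DUSP6 -2.41, IL6R 2.57), and the mesenchymal (limma, adjusted p = 0.117) and progenitor (adjusted p = 0.121) lists were no longer called.

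**Figure D2:**
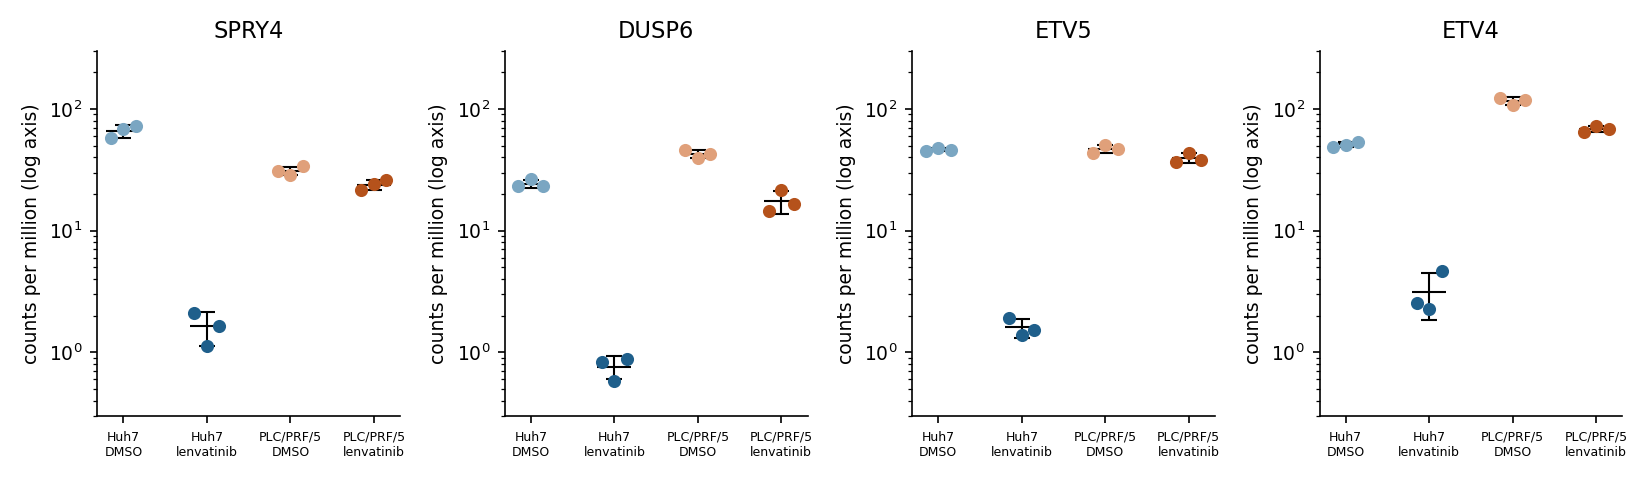
TMM-scaled CPM (log axis) of SPRY4, DUSP6, ETV5 and ETV4 in each library, by line and treatment, where points are libraries, black lines the mean and bars the SD (n = 3). SPRY4 went from 66.1 to 1.64 CPM in Huh7 and from 31.0 to 23.9 CPM in PLC/PRF/5.

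The same comparison was made in PLC/PRF/5 (n = 3 per group). The largest falls, in order, were those of CXCL1 (-2.74 ± 0.24), CXCL8 (-2.55 ± 0.19), VGF (-2.54 ± 0.27), RN7SL4P (-2.43 ± 0.59), CCL20 (-2.39 ± 0.37) and CXCL2 (-2.22 ± 0.35). CXCL1, CXCL8, CCL20 and CXCL2 are chemokines that attract leukocytes, VGF is a neuropeptide precursor and RN7SL4P a repeat-derived copy. CXCL8 went from 606 ± 6.12 to 104 ± 16.4 CPM (SD). The non-coding UCA1 (-2.11 ± 0.31), the YAP target ANKRD1 (-2.04 ± 0.23), the mucin MUC13 (-1.91 ± 0.12) and the glycoprotein hormone alpha chain CGA (-1.85 ± 0.35; DESeq2 adjusted p = 0.343) followed. The largest rise was that of LINC00205, a long non-coding RNA (4.18 ± 0.18), and the serine synthesis enzymes PHGDH (1.57 ± 0.11) and PSAT1 (1.29 ± 0.09), the neutral amino acid transporter SLC1A4 (1.46 ± 0.07), the ganglioside sialidase NEU3 (1.66 ± 0.10) and the stress-induced NIBAN1 (1.55 ± 0.31) also rose.

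Of 24 ATF4 and amino acid response genes, 17 rose, 0 fell and 7 were not called (18 and 0 adjusted over the list alone; adjusted p = 1.77e-19), ASNS at 1.17 ± 0.09. NRF2 and ferroptosis genes had 13 rises and 1 fall among 22 (14 and 3 adjusted over the list alone; adjusted p = 9.27e-10). Examples are HMOX1 at 1.24 ± 0.09 and the glutathione synthesis subunit GCLM at 1.01 ± 0.10. NF-kB and acute phase genes fell in 11 of 21 cases with no rise (1 and 13 adjusted over the list alone; adjusted p = 1.89e-09), the adhesion molecule ICAM1 at -1.44 ± 0.22. Interferon response genes fell in 10 of 18 cases with no rise (0 and 10 adjusted over the list alone; adjusted p = 1.18e-07). Among them were the ubiquitin-like ISG15 (-1.47 ± 0.09) and the RNA-binding IFIT1 (-1.09 ± 0.12). ERK output gave 7 falls and no rise among 18 genes (0 and 9 adjusted over the list alone; median -0.45, adjusted p = 2.22e-06). That call was lost at adjusted p = 0.179 with an estimated correlation. The falls included the phosphatases DUSP6 (-1.29 ± 0.17) and DUSP4 (-1.10 ± 0.10) and the early response gene IER3 (-1.57 ± 0.22). Hypoxia and glycolysis genes had 10 falls and 1 rise among 20 (1 and 12 adjusted over the list alone; adjusted p = 4.53e-07). They include lactate dehydrogenase LDHA at -0.70 ± 0.09 and hexokinase HK2 at -0.91 ± 0.12. Chaperones of the endoplasmic reticulum fell in 11 of 19 cases with no rise (0 and 12 adjusted over the list alone; adjusted p = 1.58e-06), HSPA5 at -0.56 ± 0.03, and YAP and TEAD targets in 5 of 17 with no rise (0 and 5 adjusted over the list alone; adjusted p = 6.25e-04), CCN2 at -1.80 ± 0.10. Mesenchymal genes had 1 rise and 5 falls among 14 (1 and 6 adjusted over the list alone; adjusted p = 0.00435), fibronectin FN1 at -0.66 ± 0.04, progenitor markers 5 falls among 14 (0 and 5 adjusted over the list alone; adjusted p = 0.00568), SOX4 at -0.87 ± 0.10, and FOXO and PI3K inhibition targets 1 rise and 8 falls among 15 (3 and 8 adjusted over the list alone; adjusted p = 0.00351), the metabolic kinase PDK4 at -1.13 ± 0.09.

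Hepatocyte genes split into 5 rises and 6 falls among 26 (5 and 8 adjusted over the list alone), FGA falling by 1.47 ± 0.06, FGB by 1.21 ± 0.07 and FGG by 1.04 ± 0.04. The list was called downward (adjusted p = 0.00757) although its median was 0.04, and adjusted p = 0.486 with an estimated correlation. Other receptor kinases and ligands had 1 rise and 6 falls among 14 (1 and 6 adjusted over the list alone), the FGF co-receptor KLB at -0.69 ± 0.09 and the receptor MET at -0.47 ± 0.07. Tested together they had adjusted p = 0.0159, and adjusted p = 0.0577 with an estimated correlation. As a set, the 30 cell cycle genes were not called (3 rises, 3 falls; 3 and 4 adjusted over the list alone; adjusted p = 0.773), nor were the autophagy machinery (2 rises, 11 falls of 35; 2 and 12 adjusted over the list alone; adjusted p = 0.0917), where ATG13 of the autophagy initiation complex fell (-0.83 ± 0.08), or the lysosome (4 rises, 9 falls of 30; 5 and 10 adjusted over the list alone; adjusted p = 0.156). None of the 4 measured receptor targets of lenvatinib passed the test, FGFR4 with -0.03 ± 0.13, FGFR1 with 0.26 ± 0.15, FGFR3 with 0.56 ± 0.25 and PDGFRA, which had no count in 3 of the 6 libraries, with no fold given. In all, 3133 of 15587 genes were called by edgeR, 1405 higher and 1728 lower, of which 378 changed at least 2-fold (156 higher, 222 lower), with 14 of 29 lists called and 10 with an estimated correlation, and the groups did not overlap in 40.1% of genes against 10% by chance. The share of higher genes among the calls, 44.8%, depended on the scaling: it was 63.1% with library totals alone, 62.4% with limma on log2(FPKM + 1) and 65.4% with limma on log2(TPM + 1). The remaining large changes were TSEN15 (1.43 ± 0.13), SMIM29 (1.29 ± 0.24), CT45A10 (1.44 ± 0.42), which has near-identical copies, and CAB39 (1.37 ± 0.35), with a gap of over 2-fold in a single library; the calls were lost for CT45A10 with any PLC/PRF/5 library left out (adjusted p = 0.0867 to 0.129), for CAB39 without replicate 1 or 2 with DMSO or replicate 2 or 3 with lenvatinib (adjusted p = 0.0506 to 0.0664) and for RN7SL4P without replicate 2 with lenvatinib (adjusted p = 0.0554). The endoplasmic reticulum list was not called under quantile normalization (limma, adjusted p = 0.124), nor the mesenchymal (0.0604), FOXO (0.0533) and hepatocyte (0.168) lists on log2(FPKM + 1). Exons of UCA1, ASNS, DUSP6, IER3, HK2, ISG15, ICAM1, SOX4, CCN2, FGFR1 and PDGFRA overlap another annotated gene.

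**Figure D3:**
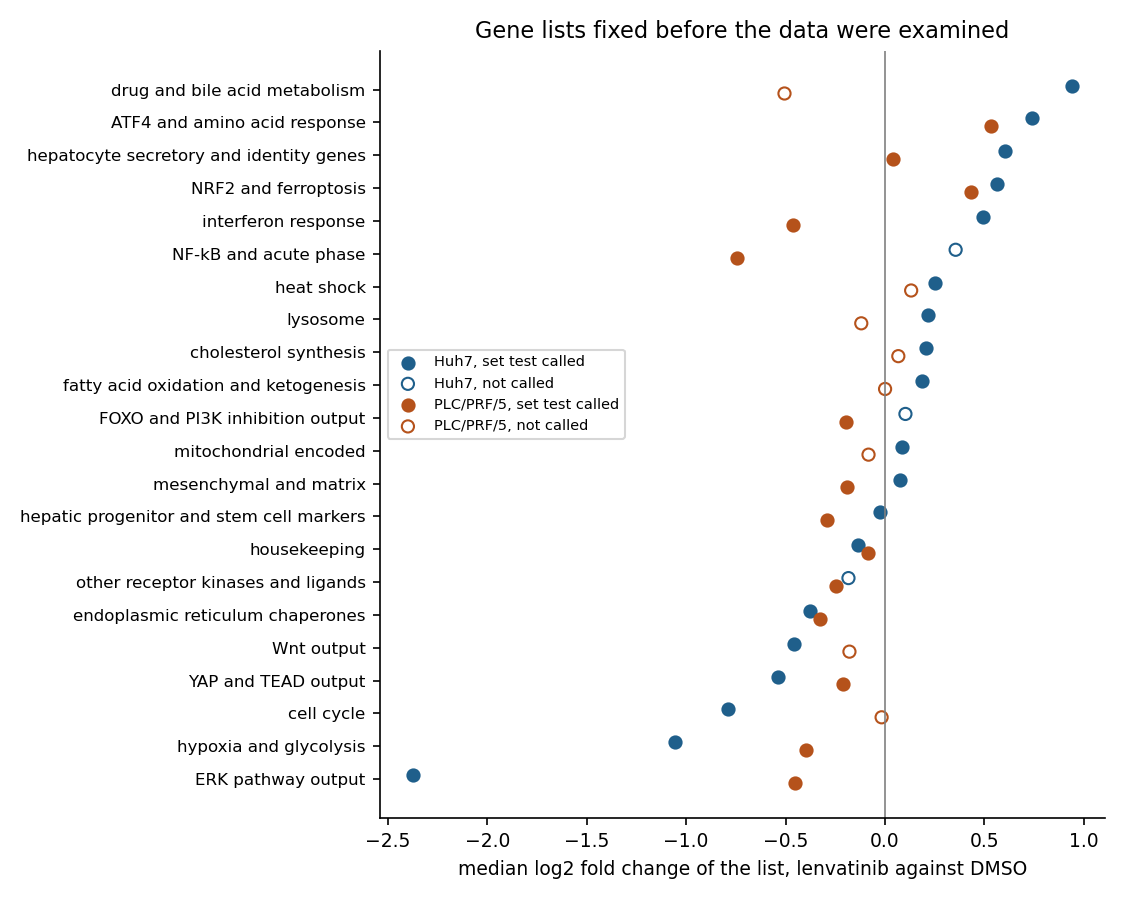
Median log2 fold change with lenvatinib of the gene lists called in at least one line, in Huh7 (blue) and PLC/PRF/5 (orange), with filled points where the set test called the list and open points where it did not. The ERK list has a median of -2.37 in Huh7 and -0.45 in PLC/PRF/5, and the cell cycle list -0.79 and -0.02.

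Whether the lines responded differently was tested as the change in PLC/PRF/5 minus that in Huh7, so that positive values mean a higher log2 fold change in PLC/PRF/5 (n = 3 per group). SPRY4 (4.96 ± 0.27), ETV5 (4.60 ± 0.17) and DUSP6 (3.69 ± 0.25) had higher log2 fold changes in PLC/PRF/5 than in Huh7, as did the matrix protein CCN2 (3.05 ± 0.14); in PLC/PRF/5, DUSP6 and CCN2 fell, while SPRY4 (-0.38 ± 0.18, adjusted p = 0.173) and ETV5 (-0.25 ± 0.11, adjusted p = 0.157) did not pass the test. The fibrinogen chains moved in opposite directions in the lines, FGG with a difference of -2.96 ± 0.06, FGA of -2.94 ± 0.08 and FGB of -3.11 ± 0.10, and kept these directions and calls in both lines under all 30 settings tried. IL6R (-4.15 ± 0.51), CXCL2 (-3.69 ± 0.52), UBD (-3.58 ± 0.46) and the neighbouring olfactory receptor pseudogene OR2I1P (-5.27 ± 0.46) had lower log2 fold changes in PLC/PRF/5, and TACC1 a higher one (3.95 ± 0.77).

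Among ERK output genes, 11 of 18 had a higher and 2 a lower log2 fold change in PLC/PRF/5 (13 and 3 adjusted over the list alone; median 1.89, adjusted p = 3.28e-31). The cell cycle list had 25 of 30 higher and none lower (26 and 0 adjusted over the list alone; median 0.87, adjusted p = 8.68e-26), MCM3 by 1.64 ± 0.10 and the topoisomerase TOP2A by 0.98 ± 0.09. With an estimated correlation the ERK and cell cycle sets both had adjusted p = 0.0127. YAP and TEAD targets (7 higher, 2 lower of 17; 8 and 2 adjusted over the list alone; adjusted p = 1.62e-08) and hypoxia and glycolysis genes (12 higher, 2 lower of 20; 12 and 2 adjusted over the list alone; adjusted p = 4.49e-07) were also higher, with the matricellular CCN1 at 2.36 ± 0.31 and PDK1 at 1.49 ± 0.11. Interferon response genes were lower in 10 of 18 cases and higher in none (0 and 13 adjusted over the list alone; median -1.06, adjusted p = 6.50e-16), ISG15 at -2.09 ± 0.12 and IFIT1 at -2.67 ± 0.17. Hepatocyte genes were lower in 9 and higher in 3 of 26 (3 and 10 adjusted over the list alone; adjusted p = 2.28e-17), drug and bile acid metabolism genes lower in 6 and higher in 1 of 11 (1 and 6 adjusted over the list alone; adjusted p = 2.73e-06), CYP1A1 at -2.72 ± 0.32 and ABCC2 at -1.17 ± 0.09, and lysosomal genes lower in 10 of 30 with none higher (0 and 15 adjusted over the list alone; adjusted p = 3.05e-06), NEU1 at -1.29 ± 0.07. NF-kB and acute phase genes were lower in 9 of 21 with none higher (0 and 12 adjusted over the list alone), CXCL8 at -2.30 ± 0.28. The set had adjusted p = 2.46e-08, and adjusted p = 0.0605 with an estimated correlation. Autophagy machinery genes were lower in 8 and higher in 1 of 35 (1 and 9 adjusted over the list alone), SQSTM1 at -1.55 ± 0.06. As a set they had adjusted p = 0.0219, and adjusted p = 0.0560 with an estimated correlation. For the ATF4 list no difference was called (5 higher, 3 lower of 24; 5 and 5 adjusted over the list alone; adjusted p = 0.789).

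In total, 2243 genes were called for the difference by edgeR, 1167 higher and 1076 lower in PLC/PRF/5, of which 663 differed at least 2-fold, with 15 of 29 lists called and 8 with an estimated correlation. The share of higher differences, 52.0%, was 47.2% with limma scaled by the median ratio, 49.0% with DESeq2 and 49.4% with edgeR on relative log expression factors. It was 61.8% with library totals alone, 61.6% and 62.5% with limma on log2(FPKM + 0.1) and log2(FPKM + 0.01), and 68.3% with limma on log2(TPM + 1). Between the lenvatinib calls of the lines, 1399 genes were called in both, 1125 in the same and 274 in opposite directions. The counts were 501 rising in both against 160 expected for independent lists, 624 falling in both against 230, 140 rising in Huh7 and falling in PLC/PRF/5 against 197, and 134 the other way against 187. Over all 15587 genes, Pearson's r of the log2 fold changes was 0.0862 and Spearman's rho 0.226, across genes, which are not independent replicates. A further 9 genes with a large fitted difference (TRIM34, LDOC1, ZNF518B, BRDT, ALPL, UGT2B15, LY6E, TNFRSF9 and MUC15) had fewer than 3 counts in at least one library of either line, so no difference is given for them. Exons of DUSP6, CCN2, UBD, OR2I1P, PDK1, ISG15 and SQSTM1 overlap another gene, and TACC1 had a gap of over 2-fold in a single library.

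**Figure D4:**
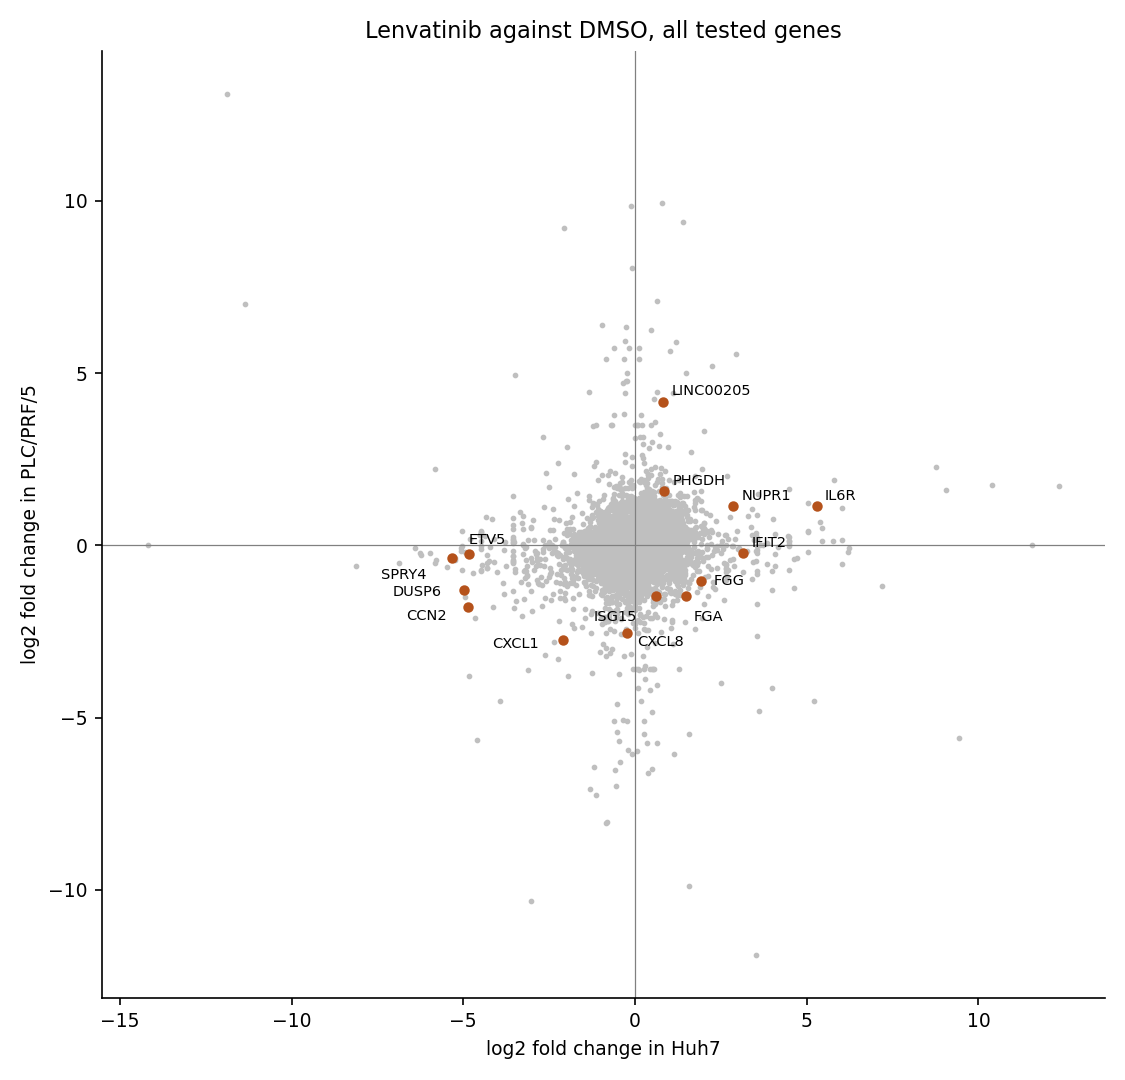
Log2 fold change with lenvatinib in PLC/PRF/5 (vertical) against Huh7 (horizontal) for the 15587 tested genes, each a point, with named genes in orange; fitted values far out are mostly of genes with few counts and are no fold estimates. SPRY4 lies at -5.34 in Huh7 and -0.38 in PLC/PRF/5, and FGA at 1.47 and -1.47.

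The lines under DMSO were compared as the background of both responses, with PLC/PRF/5 against Huh7 (n = 3 per group); line, culture and harvest cannot be separated here. Albumin (ALB) was lower in PLC/PRF/5 (-8.22 ± 0.17), at 7.53 ± 0.481 against 2245 ± 72.0 CPM (SD), as were the fetal liver protein AFP (-3.42 ± 0.10), the epithelial adhesion molecule EPCAM (-7.40 ± 0.23), the keratin KRT19 (-9.07 ± 0.32) and the intermediate filament VIM (-4.08 ± 0.15). The fibrinogen chains FGG (3.59 ± 0.04) and FGA (3.17 ± 0.06), the chemokine CXCL8 (7.96 ± 0.25), the stress cytokine GDF15 (4.93 ± 0.19) and the drug exporter ABCG2 (7.93 ± 0.42) were higher. The transcription factor TCF21 stood at 103 ± 4.25 CPM in PLC/PRF/5 and had no count in Huh7 with DMSO, at least 2468-fold higher against a floor of 3 counts per library, and the co-stimulatory receptor CD40 at 78.4 ± 3.11 CPM was at least 1886-fold higher. Conversely, the potassium channel KCNJ16 stood at 67.3 ± 0.372 CPM and the testis bromodomain gene BRDT at 58.0 ± 1.70 CPM in Huh7 with no count in PLC/PRF/5, at least 1579-fold and 1360.0-fold lower in PLC/PRF/5.

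NF-kB and acute phase genes were higher in PLC/PRF/5 in 19 of 21 cases and lower in 2 (19 and 2 adjusted over the list alone; median 5.998, adjusted p = 5.77e-13), complement C3 at 2.75 ± 0.04. Interferon response genes were higher in 17 of 18 with none lower (17 and 0 adjusted over the list alone; median 2.43, adjusted p = 5.80e-08), IFIH1 at 3.80 ± 0.18. With an estimated correlation the NF-kB and interferon sets both had adjusted p = 0.0374. Endoplasmic reticulum chaperones were higher in 14 and lower in 3 of 19 (15 and 3 adjusted over the list alone; adjusted p = 2.86e-05), HSPA5 at 1.15 ± 0.03, and YAP and TEAD targets higher in 5 and lower in 10 of 17 (5 and 11 adjusted over the list alone; adjusted p = 0.00127), CCN2 at -2.61 ± 0.10 (limma on log2(FPKM + 1), adjusted p = 0.0742). All 13 mitochondrially encoded genes were higher (13 and 0 adjusted over the list alone; adjusted p = 8.04e-06), MT-ND1 by 1.09 ± 0.04. Their set had adjusted p = 0.232 with an estimated correlation. Ribosomal protein genes were lower in 25 and higher in 5 of 35 (5 and 25 adjusted over the list alone), RPSA at -2.09 ± 0.05. Tested together they had adjusted p = 3.76e-04, and adjusted p = 0.373 with an estimated correlation. Hypoxia and glycolysis genes were lower in 14 and higher in 3 of 20 (3 and 14 adjusted over the list alone), LDHA at -1.90 ± 0.09. The set had adjusted p = 0.00215, and adjusted p = 0.197 with an estimated correlation. Cholesterol synthesis genes were lower in 14 and higher in 5 of 25 (6 and 14 adjusted over the list alone), HMGCS1 at -3.30 ± 0.04. As a set they had adjusted p = 0.0147, and adjusted p = 0.335 with an estimated correlation. The lysosome and NRF2 lists were called higher in PLC/PRF/5, each at adjusted p = 0.0226. Called lower were the cell cycle, fatty acid synthesis and mesenchymal lists, each at adjusted p = 0.0226, and the Wnt list at 0.0431. With an estimated correlation none was called, at adjusted p = 0.197, 0.197, 0.537, 0.373, 0.149 and 0.197 in that order. ERK output was not called as a set (9 higher, 3 lower of 18; 9 and 3 adjusted over the list alone; adjusted p = 0.343), SPRY4 at -1.09 ± 0.18 and PHLDA1 at 2.67 ± 0.13. Of the lenvatinib targets, FGFR4 did not pass the test (0.19 ± 0.13, adjusted p = 0.217), FGFR1 was higher (1.27 ± 0.16) and FGFR3 lower (-1.90 ± 0.26) in PLC/PRF/5. In total, 10431 of 15587 genes were called by edgeR, 5279 higher and 5152 lower, and 5291 differed at least 2-fold, with 14 of 29 lists called and 4 with an estimated correlation; with limma on log2(TPM + 1) the share of higher genes was 38.1% in place of 50.6%. Further genes listed with no count in one line were SPESP1, POF1B, SAGE1, CTAG2, ANKRD26P1 and, with near-identical copies, SSX2 and SSX2B in Huh7, and TMEM176B, TNFRSF11B, ISX, LGALS14 and, with near-identical copies, ANXA8L1 in PLC/PRF/5, while ADAMTS12 had 206 ± 0.482 CPM in Huh7 and 3 counts in all in PLC/PRF/5. APOOL and the readthrough RPL17-C18orf32, also on that list, had gaps of over 2-fold in a single library. Exons of both, and of TCF21, SPESP1, TMEM176B, ANXA8L1, VIM, CCN2, PHLDA1, HMGCS1 and FGFR1, overlap another annotated gene.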

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

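The tests of the FPKM to count ratio, of the count interval and of whole numbers, and the scaling and slope tests of the ERK pattern, were chosen after the result was seen.

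STX6 was 5.61-fold higher with lenvatinib in Huh7 and 4.49-fold higher in PLC/PRF/5 in the FPKM, where the test first planned called it, and was not called in the counts that the comparisons reported rest on. A library-dependent gene length is argued against, because only 2 of 11979 genes with at least 100 counts in every library (STX6 and FAM217B) had a FPKM to count ratio that moved by over 0.2 log2. A rise of the transcript by the FPKM fold is argued against in Huh7, where the upper 95% limit of the count change is 0.20 against 2.49, if the counts are right; in PLC/PRF/5 the limit is 2.05 against 2.17. All 9 values of STX6 and FAM217B off the count-implied FPKM by over 1 were off by a whole number to within 0.0152. The 15 other values of these genes differed from it by at most 0.0286. Among 24882 genes scanned, only STX6 and FAM217B had values off by over 0.5 and over 30%. The offsets were about 30 for STX6 in 5 lenvatinib libraries, 40 in another, 6 in a DMSO library, and -2.98 and 9.999 for FAM217B. The FPKM rise of STX6 thus lies in these offsets and not in the counts, and a whole number added to single FPKM values is the candidate explanation. How this came about was not tested. Reads moved to a neighbouring gene could not be weighed, as only 55.6% of the annotated genes within 100 kb are in the table.

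ERK output fell further in Huh7 than in PLC/PRF/5, with a median difference of 1.89 called by the test of the difference. Library scaling moves all genes about alike, and is argued against, since 5 other scalings moved the median difference of all genes by at most 0.098, below the lower quartile of 0.495 among the 18 list genes. This test replaces the planned one, whether the list stayed called, which compares the list with all other genes and so hardly responds to scaling. A uniform weaker response of PLC/PRF/5, as from less active drug, would give these lists about the same slope of PLC/PRF/5 on Huh7 changes. That slope was 0.169 for ERK output, 0.550 for the ATF4 and NRF2 lists together and 0.617 for the endoplasmic reticulum chaperones. By this measure each of them changed less in PLC/PRF/5 than in Huh7, ERK output the least. The ratio of the ERK slope to that of the ATF4 and NRF2 lists was 0.308 (95% interval 0.168 to 0.509). That interval comes from resampling genes, which are not independent, and not libraries. The ATF4 and NRF2 lists were picked after the result was seen, and both were called upward in both lines. The ratio thus argues against a uniform weaker response for these lists only. It does not argue against a weaker response of PLC/PRF/5 that differs in size between lists. A dose response that is not linear, and a difference between the lines themselves, may underlie the further ERK fall in Huh7. Both stay open and untested.

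The test of the difference called 2243 genes. SPRY4 (4.96), ETV5 (4.60) and TACC1 (3.95) had higher log2 fold changes in PLC/PRF/5, and OR2I1P (-5.27), IL6R (-4.15), CXCL2 (-3.69) and UBD (-3.58) lower ones. The lists called for the difference had median differences of 0.87 for cell cycle, 0.55 for hypoxia and glycolysis, 0.49 for YAP and TEAD, -0.45 for hepatocyte genes, -1.17 for drug metabolism, -1.06 for interferon and -0.23 for the lysosome. They were -1.48 for NF-kB (adjusted p = 2.46e-08, and adjusted p = 0.0605 with an estimated correlation) and -0.094 for autophagy (0.0219 and 0.0560). In the same order of values, they were -0.20 for fatty acid oxidation (adjusted p = 0.00820, and adjusted p = 0.141 with an estimated correlation), -0.14 for NRF2 and ferroptosis (0.0275 and 0.168), -0.22 for mitochondrial genes (0.00229 and 0.382, turning direction under quantile normalization), -0.14 for ribosomal proteins (0.0276 and 0.564) and -0.88 for histones (0.0212 and 0.185).

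For the difference, 2 of 100 splits of the libraries within the lines (of 200 possible) called as many genes as the real 2243, the real one included. These splits mix lenvatinib with DMSO and so remove the drug response itself. They therefore cannot tell whether a difference between the lines arose by chance. Splits that kept the true Huh7 labels and mixed those of PLC/PRF/5 called 733 to 1104 genes. The highest other split, 4639 genes, exchanges lenvatinib and DMSO in 1 line and so tests the sum of both responses, a structure of the samples. In Huh7, 1 of 10 splits called as many genes (3850, highest other 4), in PLC/PRF/5 1 of 10 (3133, highest other 7) and under DMSO 1 of 10 (10431, highest other 0); 10 splits are too few for a share under 0.05.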

How the results depend on the processing

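The limma fit of log2(FPKM + 1), the test first planned, was added as an alternative once the table was seen to hold counts, and DESeq2, other edgeR factors, filterByExpr and the fit without gap genes were also chosen after the data were seen. Of the counts of calls, 239 stayed within 1.5 times and 14 moved. For the named genes, 14962 cases kept their call or lack of a call, 641 lost a call (weaker) and 194 gained a call (stronger). In 26 the sign turned with a call on either side (reversed). The cause was not tested. These labels ignore the size of the change, and a sign change without a call counts as the same. By the same labels, 86 STX6 cases were the same, 16 stronger and 9 reversed. All 25 that changed come from limma on FPKM or TPM, a split whose explanations are weighed with the STX6 pattern. Calls ran to 4581, 3936, 3087 and 10674 (Huh7, PLC/PRF/5, difference, DMSO) with DESeq2 and to 4140, 3619, 2783 and 10632 with limma on log2(FPKM + 1), sharing 3835, 3126, 2234 and 10402, and 3504, 2538, 1993 (2 in the opposite direction) and 10295 with those reported. With the replicate block they were 3187, 2359, 1647 and 9700, with 820 called in both lines in the same direction (1125 reported) and 3011, 2218, 1506 and 9417 shared. Leave-one-out counts ran from 2994 to 3859, 2225 to 3283, 1782 to 2307 and 9871 to 10494, and from 854 to 1075 for genes called in both lines in the same direction. A fit of only the groups compared gives no value for the difference. At 70236175 to 75820318 counts, depth limits genes near the floor of 3 counts per library.

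With a fold of at least 2, the counts were 702, 378, 663 and 5291, and 46 called in both lines in the same direction. With an estimated correlation, 12 lists were called in Huh7, 8 for the difference and 4 under DMSO. Under DMSO, 8 lists were called with limma on log2(FPKM + 1), 8 with + 0.1, 8 with + 0.01, 9 with TPM, 8 with the median ratio and 7 with quantile normalization; TPM moved the median of all genes by -0.235. STX6, in the order + 1, + 0.1, + 0.01, TPM, median ratio, quantile, no trend and quality weights, was 2.32, 2.47, 2.49, 2.42, 2.32, 2.31, 2.32 and 2.33 in Huh7, 2.06, 2.16, 2.17, 2.15, 1.996, 2.13, 2.06 and 2.07 in PLC/PRF/5, and 0.47, 0.52, 0.53, 0.26, 0.46, 0.42, 0.47 and 0.47 under DMSO. Its difference was -0.32 with the median ratio and was called there (limma, adjusted p = 0.0493). Genes with libraries under the floor of 3 counts (LDOC1, ZNF518B and TNFRSF9) have no measured difference, so their change of sign is not a reversal: the fitted value for LDOC1 was -0.32 (+ 1), -0.032 (+ 0.1), -0.22 (TPM), -0.38 (median ratio), -0.37 (quantile), -0.32 (no trend) and -0.33 (weights). For ZNF518B it was -0.11, -0.016, -0.071, -0.17, -0.17, -0.11 and -0.11 in that order. For TNFRSF9 it was 0.23 (+ 1), 0.17 (median ratio), 0.17 (quantile), 0.23 (no trend) and 0.24 (weights). LUM turned for the difference to 0.46 (+ 1), 0.46 (no trend) and 0.50 (weights). Under quantile normalization HSP90AA1 (0.056) and MT-ND3 (0.011) turned for the difference, and MT-ND2 (0.00) and MT-ND6 (0.11) in PLC/PRF/5.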

Other observations

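The definition of gaps in single libraries was chosen after the data were seen. Among FOXO and PI3K inhibition targets, 3 rose and 4 fell of 15 in Huh7 (5 and 5 adjusted over the list alone; adjusted p = 0.542), with the glucose-responsive TXNIP at -1.59 ± 0.07. The PLC/PRF/5 counts were 1 up and 8 down (3 and 8 adjusted over the list alone; adjusted p = 0.00351). For p53 targets, 2 rose and 3 fell of 17 in Huh7 (4 and 3 adjusted over the list alone; adjusted p = 0.838), with the stress cytokine GDF15 at 0.88 ± 0.17. There were 0 up and 1 down in PLC/PRF/5 (0 and 1 adjusted over the list alone; adjusted p = 0.734), with GDF15 at -1.42 ± 0.17. In the BCL2 family, 0 rose and 1 fell of 11 in Huh7 (0 and 1 adjusted over the list alone; adjusted p = 0.946), with the survival factor BCL2L1 at -1.84 ± 0.13. PLC/PRF/5 had 1 up and 2 down (3 and 4 adjusted over the list alone; adjusted p = 0.381), with BCL2L1 at -0.68 ± 0.13. Of fatty acid synthesis genes, 3 rose and 3 fell of 11 in Huh7 (3 and 3 adjusted over the list alone; adjusted p = 0.617), with the acetyl-CoA synthetase ACSS2 at 0.71 ± 0.07. The PLC/PRF/5 counts were 4 up and 2 down (4 and 3 adjusted over the list alone; adjusted p = 0.162), with malic enzyme ME1 at 0.62 ± 0.07. Of fatty acid oxidation genes, 5 rose and 2 fell of 19 in Huh7 (5 and 2 adjusted over the list alone; adjusted p = 0.0348), with CPT1A at 0.79 ± 0.05, and adjusted p = 0.199 with an estimated correlation. There were 1 up and 5 down in PLC/PRF/5 (1 and 5 adjusted over the list alone; adjusted p = 0.223). Of Wnt targets, 2 rose and 6 fell of 12 in Huh7 (3 and 7 adjusted over the list alone; adjusted p = 0.0492), with the transcription factor MYC at 1.39 ± 0.28, and adjusted p = 0.116 with an estimated correlation. PLC/PRF/5 had 0 up and 1 down (0 and 1 adjusted over the list alone; adjusted p = 0.282). Other receptor kinases and ligands in Huh7 had 3 rises and 5 falls of 14 (3 and 5 adjusted over the list alone; adjusted p = 0.617), with the adaptor IRS1 at -0.74 ± 0.06. NF-kB and acute phase genes in Huh7 had 6 rises and 1 fall of 21 (7 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.0751). The 1 fall was that of the chemokine CXCL1 (-2.11 ± 0.28).

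For mitochondrially encoded genes, 4 rose and 0 fell of 13 in Huh7 (6 and 0 adjusted over the list alone; adjusted p = 0.0492), turning direction under quantile normalization, and adjusted p = 0.558 with an estimated correlation. The PLC/PRF/5 counts were 0 up and 5 down (0 and 6 adjusted over the list alone; adjusted p = 0.0917). Yet the share of all mitochondrial transcripts in the unscaled counts of that line was 10.5% with DMSO and 11.1% with lenvatinib. The direction in PLC/PRF/5 thus depends on the scaling or on the genes included. Of housekeeping genes, 1 rose and 5 fell of 13 in Huh7 (2 and 5 adjusted over the list alone; adjusted p = 0.0314), with GAPDH at -0.46 ± 0.05, and adjusted p = 0.159 with an estimated correlation. There were 0 up and 5 down in PLC/PRF/5 (1 and 5 adjusted over the list alone; adjusted p = 0.0159), with GAPDH at -0.82 ± 0.05, and adjusted p = 0.124 with an estimated correlation. For ribosomal proteins, 3 rose and 1 fell of 35 in Huh7 (1 and 0 adjusted over the list alone; adjusted p = 0.330). PLC/PRF/5 had 2 up and 10 down (2 and 11 adjusted over the list alone; adjusted p = 0.0917). Of histone genes, 2 rose and 0 fell of 8 in Huh7 (4 and 0 adjusted over the list alone; adjusted p = 0.110). The PLC/PRF/5 counts were 0 up and 2 down (0 and 2 adjusted over the list alone; adjusted p = 0.208). In PLC/PRF/5, cholesterol synthesis (5 rises, 2 falls of 25; adjusted p = 0.175), heat shock (2 rises, 1 fall of 14; adjusted p = 0.156) and drug metabolism (1 rise, 2 falls of 11; adjusted p = 0.282) were not called. Too few members were measured for a set test of lenvatinib receptors (4), fibroblast (3), endothelial (1) and leukocyte markers (4), of which 1, 1, 0 and 1 were called in Huh7 and 0, 2, 1 and 0 in PLC/PRF/5.

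A gap of over 2-fold between a library and the mean of the other 2 of its group was seen in 550 of 10446 genes, as 795 pairs of gene and library (505 down, 290 up), with 57 to 76 genes per library, STX6 among them. Simulated libraries, in which all genes of a given level shared the same spread, gave 23.3% as many pairs. Genes with a wider spread of their own were not simulated, so chance spread between replicates stays open. Reads moved between overlapping genes may account for part, as 45.4% of gap genes overlap another gene against 39.4% of matched genes (permutation p = 0.0021), though the partner offset at least 0.5 of the change in 23 of 191 pairs. Depth stays open, with r = -0.267 (95% interval -0.729 to 0.363; permutation p = 0.394) between gap genes and total counts over 12 libraries. No biological explanation was tested.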
